A study of Mus musculus with 10 samples.

How the data were processed

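The data were RNA sequencing libraries of tumour-infiltrating CD4+CD25- T cells from PyMT mice, which develop mammary tumours, on the C57BL/6 strain at 23 weeks of age. There were 4 genotypes with 2 replicates each: wild type (WT, floxed Tgfbr2 without Cre), KO (Tgfbr2 deleted by a ThPOK-Cre transgene, active in the CD4 lineage), Il4null (Il4-deficient) and Il4null_KO (both). Each KO replicate had a first library and a repeat library made from its RNA, which gave 10 libraries for 8 replicates. Per the labels' protocols, cells were sorted from digested tumours into Trizol, RNA was amplified with the SMART-Seq v4 kit, and libraries were prepared with the KAPA Hyper Prep kit. This amplification does not use molecular identifiers, so read counts were not counts of molecules. The labels do not say whether the replicates of a genotype came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

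Per the submitters' processing notes, reads were handled with bcl2fastq 2.18.0 and STAR, the genome build was mm10, and DESeq2 was used. The read counter, its annotation and any filter on genes were not given in the sources used here, and neither was whether strand was used in counting. The deposited signal per gene and library was a read count divided by 1 size factor per library. All values (100%) were whole multiples of the smallest value above 0 in their library, within 0.001 reads, which recovered the reads. Recovered totals ran from 17121030 to 33802781 reads per library, and 1 read was worth 0.644 to 1.47 normalized counts. At that depth, a value of 0 allowed up to 3 reads, or 1.93 to 4.41 normalized counts, a bound that covers counting error only. The table held 17370 rows, of which 7 had no gene name and were left out. Those 7 rows held between 0.0029% and 0.0205% of each library.

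Everything that follows was computed from the deposited signal. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low counts. Genes with at least 10 normalized counts in at least 2 of the 8 replicates were tested, which left 14473. The libraries of a KO replicate were averaged, and all 4 genotypes shared one estimate of the spread, with 4 residual degrees of freedom. The comparisons were KO with WT, Il4null_KO with Il4null, Il4null_KO with KO, Il4null with WT, and the interaction of Tgfbr2 deletion with the Il4 background. A mean effect of Tgfbr2 deletion over both backgrounds was added after the data had been seen.

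Before the data were examined, 29 gene lists with 379 distinct genes were fixed: 15 of T cell states, 1 of T cell identity, 2 of RNA quality and 11 of other cell types. Of those genes, 34 were not found in the table. Some lists shared members, such as Tgfb1 in the TGF-beta response and tissue repair lists, so their results were not fully separate. The lists were tested with camera in limma at a preset inter-gene correlation of 0.01 where at least 3 members were tested, and again with the correlation estimated from the data. This left 27 lists. The CD8 T cell list had 2 members, and no member of the list of mitochondrially encoded genes was found in the table, so neither was tested.

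Named genes followed a rule fixed at the same time as the lists. It took Tgfbr2, Il4, Il5 and Il13 first. It then took up to 8 genes with the largest rise and 8 with the largest fall past the threshold, provided that they reached 50 normalized counts in the higher group and that no library of one group overlapped the other. Where none qualified, it took the 3 such genes with the smallest p in each direction. From each state list it took the members past the threshold or, with none, at most 2 by smallest p. Gene positions came from a GENCODE annotation of the same mm10 build.

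Alternatives covered the pseudocount, the filter, quantile normalization, TMM rescaling, the variance trend, the genotypes in the fit, the use of the KO libraries, a replicate block and leaving out each replicate. The quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0 were run on the recovered reads. Alternatives chosen after seeing the data were a term for the depth set of each library, KO replicate 2 without its repeat library, removal of a trend on transcript length, and the mean of the mammary and tumour epithelium list as a covariate. In the alternatives that used all 10 libraries, with or without the term for the depth set, lists were tested with cameraPR instead of camera. It takes the moderated t values of the fit at the same preset correlation. Figures were drawn with matplotlib 3.10.9.

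The pipeline was tested on simulated data. Counts for the 14473 genes were drawn with the libraries' means, sizes and dispersions, and 200 genes were changed between KO and WT. The changed genes all had a mean log2 value above 7, so recovery of genes with lower counts was not tested. Each KO replicate was drawn once at the summed depth of its 2 libraries, so the difference between libraries of one RNA was not simulated. The limma fit recovered 18 of 100 genes changed 4-fold and 74 of 100 changed 16-fold, with 7 false calls. At a dispersion of 0.05 it recovered 100 of 100 at both sizes, with 17 false calls. A simulated list of 20 raised genes passed camera in both cases, and 0 of 50 unchanged lists did. Genes were independent in this simulation, so it does not test camera on correlated genes.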

Results

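Gene expression was measured in CD4+CD25- T cells sorted from PyMT breast tumours of 4 genotypes. The design addressed how loss of the TGF-beta receptor gene Tgfbr2 in CD4 T cells changes these cells, and whether Il4, which encodes the type 2 cytokine IL-4, matters for it. WT, KO, Il4null and Il4null_KO had 2 replicates each, and each KO replicate had 2 libraries. The libraries fell into 2 sets by depth. WT and the first KO libraries held 17121030 to 18479090 reads, while the KO repeats, Il4null and Il4null_KO held 28003231 to 33802781. Pearson correlations of log2 values between libraries were 0.865 and 0.905 for the pairs made from one RNA, 0.804 to 0.894 within a genotype and 0.769 to 0.904 between genotypes. Chi-square per degree of freedom, which covers counting error only and takes amplified reads as independent, was 67.8 and 212 for the pairs made from one RNA. It was 112 between the first KO libraries and 306 between the WT libraries. The repeat library of KO replicate 2 stood apart, at 226 on the first principal component against -89.5 to 69.2 for the others, and had the fewest genes detected (12459) and the largest share of reads in its 10 highest genes (6.70%).

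The targeted genes were read first as a check of the labels. Tgfbr2 (chromosome 9, 116084293 to 116175360, mm10) had 7876 and 7894 normalized counts in WT, 6730 and 7623 in KO, 13816 and 12544 in Il4null, and 7762 and 8205 in Il4null_KO. Deletion of floxed sequence can leave reads from the rest of the gene, so this total checks little. Il4 (chromosome 11, 53602982 to 53618669) had 107 and 276 normalized counts in WT, 389 and 380 in KO, 97 and 75 in Il4null, and 99 and 40 in Il4null_KO. Reads were thus counted at Il4 in both Il4-deficient genotypes. Il5, a type 2 cytokine that supports eosinophils, had 36 and 38 normalized counts in WT, 525 and 3660 in KO, 16 and 1 in Il4null, and 681 and 15 in Il4null_KO. Il13, another type 2 cytokine, stayed at or below 11 in every replicate except KO replicate 2, with 247. None of the 4 genes passed the limma test in any comparison.

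RNA of other cell types differed between replicates of one genotype. Krt8, an epithelial keratin, had 39788 and 2873 normalized counts in the WT replicates and 2581 and 8736 in Il4null. In KO, its first libraries had 10425 and 23134 and its repeats 11549 and 32473, against 3479 and 6575 in Il4null_KO. Lyz2, a macrophage lysozyme, had 28932 in Il4null replicate 2 and at most 4934 in every other library. The neutrophil gene S100a8 had 1844 and 2210 in the libraries of KO replicate 1 and at most 318 in the others. Members of the core T cell list, such as Cd3e, were abundant in all libraries, with list means of 12.8 to 14.0 on the log2 scale. In WT replicate 1, however, the epithelium list mean (13.15), the highest of any library, lay above the core T cell mean (12.97). In Il4null replicate 2 these means were 12.55 and 12.81. Differences between genotypes also followed transcript length in each comparison, with Spearman correlations across 9824 genes of -0.31 in KO against WT, -0.25 in Il4null_KO against Il4null, 0.41 in Il4null_KO against KO, 0.38 in Il4null against WT and 0.17 in the interaction. Genes are not independent replicates. With this trend removed, the list calls lost were the stress call of Il4null against WT (adjusted p = 0.0521) and the epithelium call of the interaction (0.0842).

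**Figure D1:**
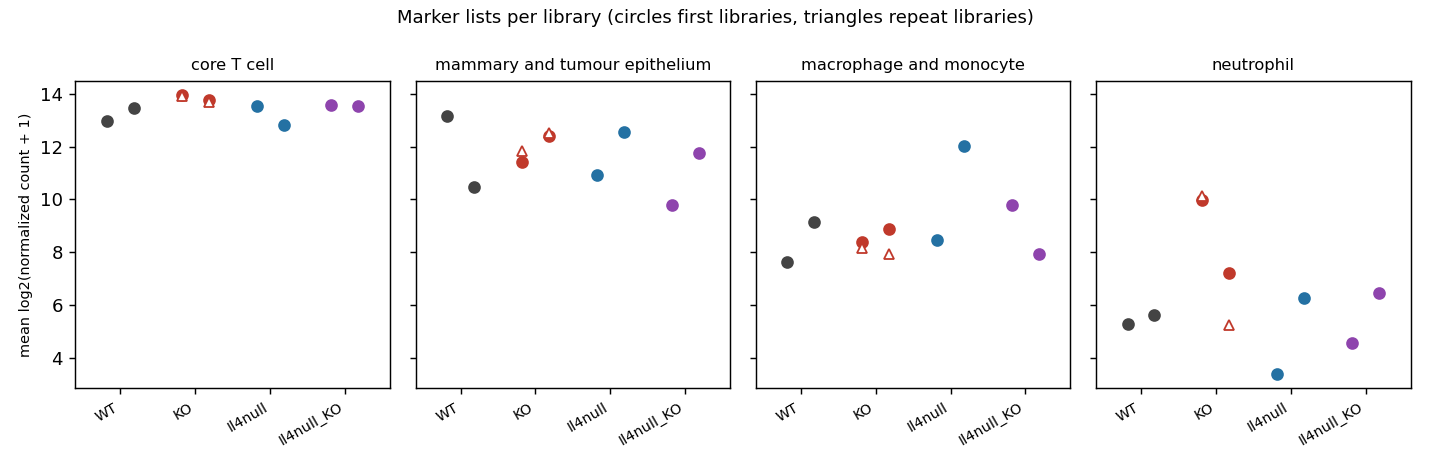
Mean log2(normalized count + 1) of the tested members of 4 marker lists in each library, by genotype. Circles are first libraries and triangles are repeat KO libraries. The epithelium mean ran from 9.77 to 13.1 and the neutrophil mean from 3.39 to 10.1, while the core T cell mean ran from 12.8 to 14.0.

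The comparison of KO with WT asked what Tgfbr2 deletion does where Il4 is intact. Mmp9 (chromosome 2, 164940780 to 164955850), a secreted gelatinase, rose from 92 and 108 normalized counts in WT to 3339 and 8204 in KO. Its log2 fold change was 5.70 ± 0.46 (SE, n = 2 replicates per genotype, limma adjusted p = 0.0316). Of the feedback inhibitors of TGF-beta signalling, Pmepa1 had 6580 and 5748 normalized counts in WT and 629 and 1275 in KO (log2 fold change -2.78 ± 0.43, adjusted p = 0.25) and Skil had a log2 fold change of -2.57 ± 0.54 (adjusted p = 0.296), so neither passed. Pmepa1 differed between the libraries of one RNA, with 960 and 1903 in the first KO libraries and 297 and 647 in the repeats, and its log2 fold change was -2.19 with the first libraries alone. Klrg1, an inhibitory receptor of effector and NK cells, had 339 and 206 in WT and 2860 and 5210 in KO (log2 fold change 3.86 ± 0.40, adjusted p = 0.093). Ahr, a ligand-activated transcription factor, had 3209 and 4511 in WT and 681 and 685 in KO (log2 fold change -2.48 ± 0.35, adjusted p = 0.25).

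Of 14473 genes, 1 passed limma in KO against WT, while 1749 had an unadjusted p under 0.05 and 724 would by chance. That number depended on single replicates, at 856 without KO replicate 2 and 2619 without WT replicate 1, and was 834 with only the genotypes compared and 962 with a term for the library set. edgeR called 0 and DESeq2 called 527, of which 243 were higher and 284 lower in KO. The Mmp9 call was lost in all 8 fits that left out 1 replicate, with adjusted p from 0.0508 to 0.273, while its log2 fold change stayed between 5.05 and 6.35. Within the shallower library set, with the first KO libraries alone, the Mmp9 log2 fold change was 5.26 (adjusted p = 0.00719). Besides Ahr, the lower genes with the smallest p were Qpct, encoding glutaminyl cyclase (log2 fold change -4.33 ± 0.60), and Nt5e, encoding an ecto-nucleotidase (-3.32 ± 0.51), both with adjusted p = 0.25. Csf2, encoding the growth factor GM-CSF, had 173 and 154 normalized counts in WT and 1921 and 2606 in KO (adjusted p = 0.296).

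Among the state lists, 11 of the 13 tested members of the TGF-beta response list were lower in KO, with a median log2 fold change of -1.65 (camera adjusted p = 0.00214, adjusted p = 0.62 with an estimated correlation). Adjusted over the list alone, 6 members fell and 2 rose, against 0 over all genes. Tgfb1, which encodes the ligand, was one of the 2 higher, with 1606 and 1851 normalized counts in WT and 4600 and 6371 in KO (log2 fold change 1.65 ± 0.28). The regulatory T cell list had a median of 1.35, the type 1 helper list 1.22, the exhaustion and checkpoint list 0.93, the IL-4 and STAT6 response list 0.92 and the hypoxia and glycolysis list 0.82. Their camera adjusted p were 0.0109, 0.000599, 0.0109, 0.000792 and 0.00482, and each had adjusted p = 0.62 with an estimated correlation. In the same order, 7 of 12, 14 of 18, 10 of 12, 11 of 13 and 11 of 17 members were higher. The regulatory T cell list was thus split, with 5 members lower and a mean of 0.68. Adjusted over the list alone, 4 regulatory T cell members passed, led by the costimulatory receptor genes Tnfrsf4 (log2 fold change 1.98 ± 0.45) and Tnfrsf9 (2.23 ± 0.52). In the IL-4 and STAT6 list 1 passed, Jak3 (1.52 ± 0.37), and in the type 1 helper, exhaustion and hypoxia lists 0 did. Type 1 members with the smallest p were Ccl5, a chemokine gene with 3912 and 5002 normalized counts in WT and 26290 and 14918 in KO, and Tbx21, which encodes T-bet (log2 fold change 1.40 ± 0.53). The checkpoint gene Lag3 had 22 and 62 in WT and 869 and 169 in KO.

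The interferon-stimulated list was lower in KO, with 16 of 18 members lower and a median of -0.78 (camera adjusted p = 0.00399, adjusted p = 0.62 with an estimated correlation). Its members Ifi44 (log2 fold change -3.21 ± 0.71) and Ifit3 (-1.72 ± 0.42) passed when adjusted over the list alone. The type 2 helper list had a median of 1.16 and did not pass (camera adjusted p = 0.0635). Adjusted over the list alone, 3 of its members passed: Il1rl1, the IL-33 receptor gene, was higher (log2 fold change 2.01 ± 0.54), Ccr8, a chemokine receptor gene, was lower (-2.38 ± 0.58), and 1 more was higher. With these lists, the core T cell list was higher by a median of 0.69 (camera adjusted p = 0.000599) and the neutrophil list, to which Mmp9 itself belongs, by 3.12, with all 8 members higher (camera adjusted p = 0.000599). Each had adjusted p = 0.62 with an estimated correlation.

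Without WT replicate 1 the core T cell, type 1, regulatory, exhaustion and IL-4 calls were lost (adjusted p = 0.217, 0.329, 0.262, 0.487 and 0.234), and without WT replicate 2 the hypoxia call (0.334). Without KO replicate 1 the TGF-beta, type 1, exhaustion and neutrophil calls were lost (0.0548, 0.204, 0.811 and 0.101), and without KO replicate 2 the interferon call (0.505). Of these 11 lost calls, 3 kept a median within 1.5 times of the full value, namely TGF-beta (-1.45), core T cell (0.60) and regulatory (1.03). The medians shrank by more in the other 8, to 0.18 for IL-4, 0.16 for hypoxia, -0.27 for interferon, 1.48 for neutrophil, 0.63 and 0.42 for type 1, and 0.53 and -0.0016 for exhaustion genes. With the first KO libraries alone, the medians were -1.65 for the TGF-beta list, 1.16 for the regulatory T cell list, 1.22 for type 1, 0.86 for exhaustion, 0.72 for IL-4 and STAT6, 0.73 for hypoxia, -0.48 for interferon, 0.81 for core T cell and 3.25 for neutrophil genes, and all 9 calls held. List calls were frequent in other groupings too. In fits of the 4 replicates of each pair of genotypes, the real grouping called 6 to 13 lists over the 4 comparisons and the 8 other groupings of the same replicates called 4 to 14.

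**Figure D2:**
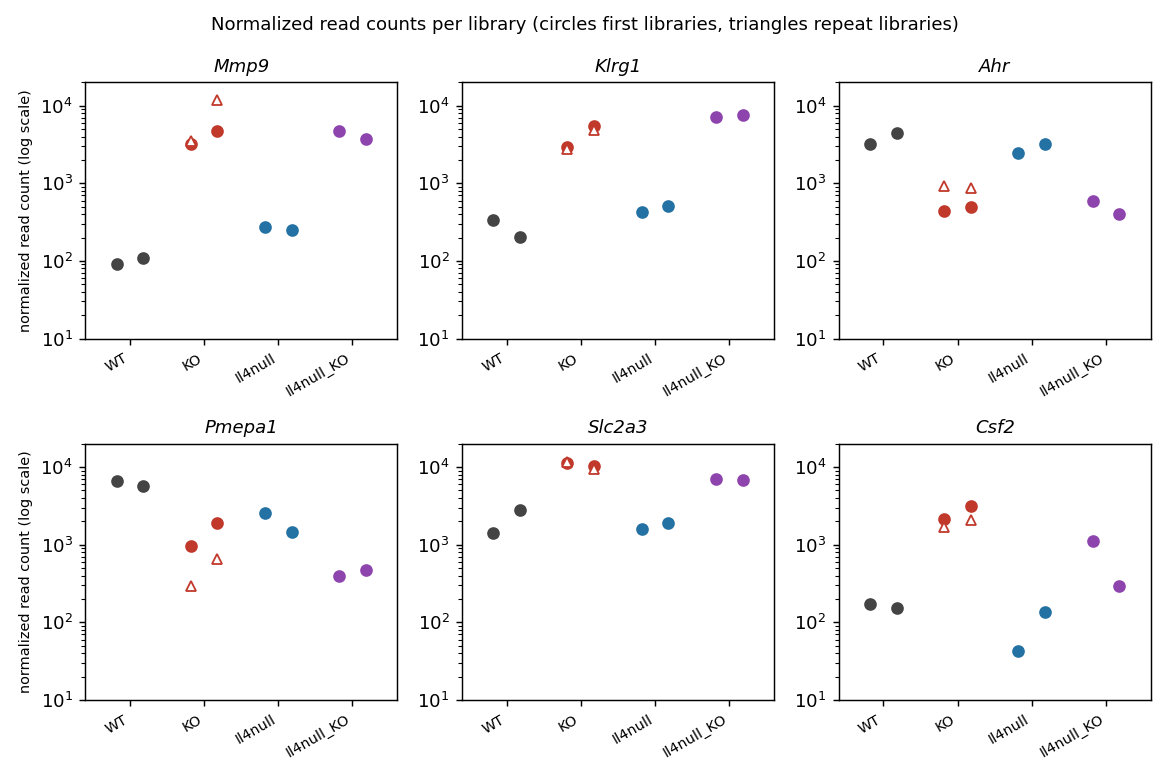
Normalized read counts of 6 genes in each library on a log scale, by genotype. Circles are first libraries and triangles are repeat KO libraries. For Mmp9 and Klrg1 the KO and Il4null_KO libraries all lie above the WT and Il4null libraries, with Mmp9 at 3205 or more against 276 or less, and for Ahr they all lie below.

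The comparison of Il4null_KO with Il4null asked the same of Tgfbr2 deletion on an Il4-deficient background. Klrg1 (chromosome 6, 122270596 to 122282882) had 428 and 515 normalized counts in Il4null and 7198 and 7600 in Il4null_KO (log2 fold change 3.97 ± 0.40, limma adjusted p = 0.152). Mmp9 had 276 and 249 in Il4null and 4714 and 3726 in Il4null_KO (log2 fold change 3.99 ± 0.46, adjusted p = 0.212). Slc2a3, a glucose transporter gene, had 1614 and 1911 against 6945 and 6752 (log2 fold change 1.96 ± 0.35). Ahr had 2437 and 3200 against 595 and 402 (log2 fold change -2.51 ± 0.35, adjusted p = 0.477). Among the lower genes with the smallest p was also Hoxb2, a homeobox gene with 143 and 146 in Il4null and 0 in both Il4null_KO replicates.

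No gene passed limma in Il4null_KO against Il4null, and 471 had an unadjusted p under 0.05 (405 to 581 in the fits that left out 1 replicate). The main count of 471 was below the 724 that would by chance. edgeR called 0 and DESeq2 called 51. Klrg1 passed limma with quantile normalization (adjusted p = 0.0205), all 10 libraries (0.023) and the epithelium covariate (0.0199). Without the repeat library of KO replicate 2, left out after the data had been seen, limma called Mmp9 alone (adjusted p = 0.0446).

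The TGF-beta response list was lower in Il4null_KO in 12 of 13 members, with a median of -1.70 (camera adjusted p = 4.47e-11, adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, 5 members fell, led by Pmepa1 (log2 fold change -2.17 ± 0.43) and Smad7, an inhibitor of the receptor (-2.36 ± 0.48). The cell cycle list was higher in 20 of 22 members, with a median of 0.91 (camera adjusted p = 2.1e-13, adjusted p = 0.548 with an estimated correlation). Ccna2 (1.43 ± 0.49) and Ccnb2 (1.22 ± 0.42), which encode mitotic cyclins, led it, and 0 members passed when adjusted over the list alone. The type 17 helper list was lower, with a median of -1.16 (camera adjusted p = 0.000291, adjusted p = 0.548 with an estimated correlation), and Ahr alone passed over the list.

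The cytotoxic and NK receptor list had a median of 0.82 (camera adjusted p = 0.00557, adjusted p = 0.658 with an estimated correlation), and Klrg1 passed when adjusted over the list alone. Gzma, a granzyme gene, had 2398 and 1686 normalized counts in Il4null and 6835 and 4112 in Il4null_KO. The type 1 helper, regulatory T cell and core T cell lists were higher, with medians of 0.64, 0.76 and 0.39 (camera adjusted p = 0.00199, 0.0148 and 0.00199), and each had adjusted p = 0.658 with an estimated correlation. In these lists 0 members passed over the list alone. The naive and central memory list was lower in 12 of 14 members, with a median of -0.35 (camera adjusted p = 0.00373, adjusted p = 0.621 with an estimated correlation). Its member Ccr7, a lymph node homing receptor gene, had 14798 and 9156 in Il4null and 4019 and 2921 in Il4null_KO. Alongside, the macrophage and monocyte list was lower by a median of -1.06 in all 14 members, and the epithelium list by -0.51. Their camera adjusted p were 0.000494 and 0.0314, and they had adjusted p = 0.658 and 0.726 with an estimated correlation.

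Without Il4null replicate 2, the library with the most macrophage RNA, the core T cell, type 1, regulatory, cytotoxic, macrophage and epithelium calls were lost (adjusted p = 0.957, 0.174, 0.17, 0.594, 0.752 and 0.752), and without Il4null replicate 1 the naive call (0.29). Without Il4null_KO replicate 1 the regulatory and epithelium calls were lost (0.936 and 0.961), without Il4null_KO replicate 2 the macrophage call (0.224), and without KO replicate 1 or 2 the epithelium call (0.0555 and 0.0527). In 8 of these 12 lost calls the median shrank by more than 1.5 times or turned. With the epithelium mean as a covariate, the core T cell, type 1, regulatory, cytotoxic and epithelium calls were lost (adjusted p = 0.226, 0.188, 0.296, 0.377 and 0.676), with medians of 0.19, 0.31, 0.43, 0.28 and 0.03. Both genotypes of this comparison lay in the deeper library set.

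Over both backgrounds, a contrast added after seeing the data, 3 genes passed limma. Mmp9 rose (log2 fold change 4.85 ± 0.33, n = 4 replicates per side, adjusted p = 0.00642), Klrg1 rose (3.92 ± 0.28, adjusted p = 0.00642) and Ahr fell (-2.49 ± 0.24, adjusted p = 0.0425), each in the same direction on both backgrounds. Ahr passed in 0 of the 8 fits that left out 1 replicate (adjusted p from 0.065 to 0.447), and was also lost without a filter (0.0515), without a variance trend (0.105), with the repeat KO libraries only (0.119) and by edgeR (0.0945). Mmp9 and Klrg1 passed in 4 of them, but not without Il4null replicate 1 (0.138 for both), Il4null replicate 2 (0.0947 for both), Il4null_KO replicate 1 (0.11 for both) or Il4null_KO replicate 2 (0.0937 and 0.0951). The log2 fold changes stayed within 4.52 to 5.17 for Mmp9, 3.70 to 4.14 for Klrg1 and -2.63 to -2.35 for Ahr. Among the other alternatives, Mmp9 and Klrg1 did not pass without a variance trend either, and a replicate block also ended the Ahr call. Calls shared by the separate comparisons could not be counted, since limma called 0 genes in Il4null_KO against Il4null. Across genes, which are not independent replicates, the log2 fold changes on the 2 backgrounds had a Pearson correlation of 0.20 and a Spearman correlation of 0.21. Over the 9966 genes with a mean log2 value above 7, these were 0.30 and 0.29. Of the 100 genes with the smallest p in KO against WT, 84 had the same sign in the other comparison. Both comparisons also followed transcript length in the same direction (Spearman correlations -0.31 and -0.25). The share over all genes was not computed, so the 84 cannot be told apart from that shared trend.

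**Figure D3:**
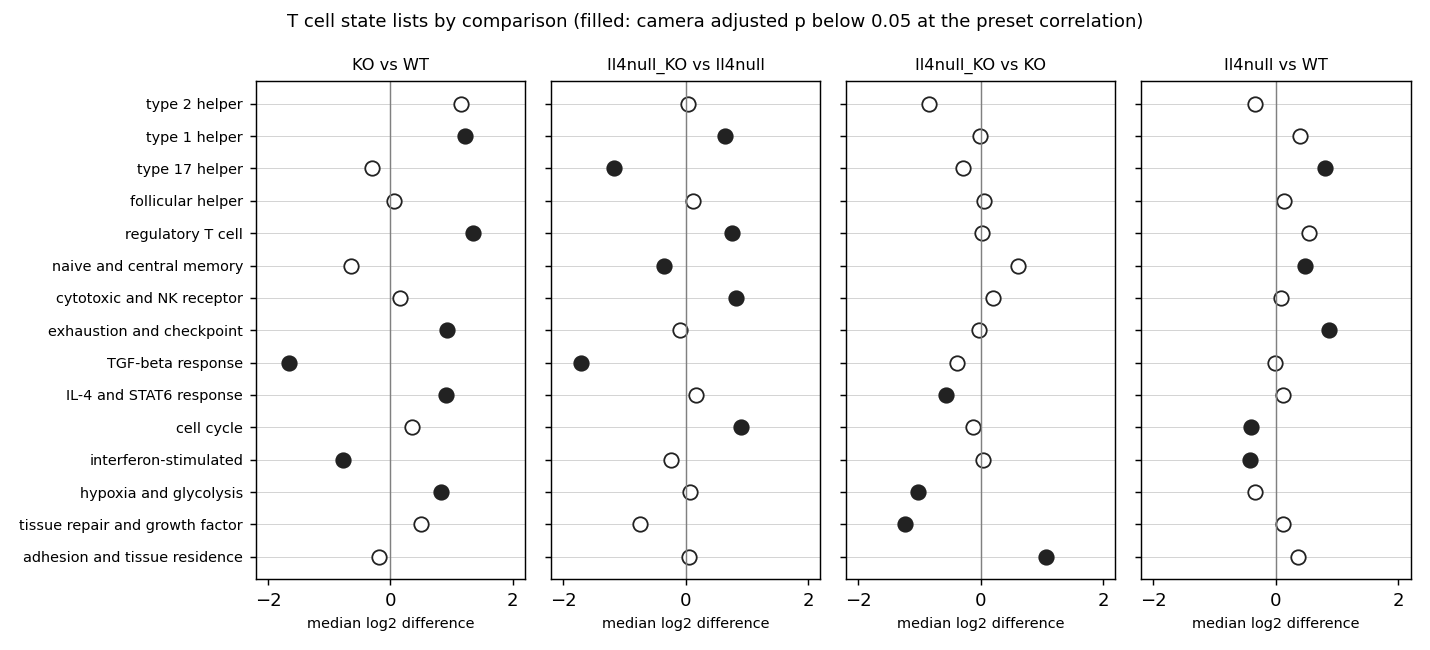
Median log2 difference of the tested members of each of 15 T cell state lists, in 4 panels by comparison. Filled points passed camera at the preset correlation, a call that no list kept with an estimated correlation. The TGF-beta response list lies at -1.65 and -1.70 in the comparisons of Tgfbr2-deleted with undeleted cells.

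The comparison of Il4null_KO with KO asked what loss of Il4 does in Tgfbr2-deleted cells. All 17 members of the hypoxia and glycolysis list were lower in Il4null_KO, with a median of -1.02 (camera adjusted p = 3.29e-05, adjusted p = 0.697 with an estimated correlation). Hk2, encoding a hexokinase, had 1060 and 508 normalized counts in KO and 251 and 85 in Il4null_KO (log2 fold change -2.32 ± 0.79), and Pgk1, another glycolytic gene, had 5738 and 3582 against 2271 and 2212. The tissue repair and growth factor list was lower in 12 of 13 members, with a median of -1.23 (camera adjusted p = 0.0043), and so was the IL-4 and STAT6 response list, in 12 of 13 members with a median of -0.56 (camera adjusted p = 0.0101). Both had adjusted p = 0.697 with an estimated correlation. The STAT-induced suppressor genes Socs1 (log2 fold change -1.26 ± 0.42) and Cish (-1.07 ± 0.37) led the IL-4 list, and Furin, encoding a proprotein convertase (-1.70 ± 0.47), and Tgfb1 (-0.99 ± 0.28) led the tissue repair list. Adjusted over the list alone, 0 members passed in any of the 3 lists.

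The adhesion and tissue residence list was higher in Il4null_KO in 11 of 15 members, with a median of 1.07 (camera adjusted p = 0.0125, adjusted p = 0.697 with an estimated correlation). Itga4, an integrin gene, had 3498 and 1615 normalized counts in KO and 10690 and 7486 in Il4null_KO, and 0 members passed over the list alone. Of other genes, Klrk1, encoding the NKG2D receptor, had 447 and 482 in KO and 2587 and 4752 in Il4null_KO, and Gzma 1894 and 1855 (averages of both libraries) against 6835 and 4112. These 2 genes and 1 more of the cytotoxic list passed when adjusted over the list alone, while the list itself did not pass (camera adjusted p = 0.104). Of the NK cell list, which did not pass either (median 0.67, camera adjusted p = 0.13), 5 of 6 members were higher, and Klri2 passed over the list alone (adjusted p = 0.0248). Il4 had a log2 fold change of -2.60 ± 0.80 (adjusted p = 0.343). The tissue dissociation stress, neutrophil and epithelium lists were lower, with medians of -1.39, -2.61 and -1.78 (camera adjusted p = 0.0152, 0.0101 and 0.0101, each adjusted p = 0.697 with an estimated correlation).

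No gene passed limma in Il4null_KO against KO, and 1687 had an unadjusted p under 0.05, but only 822 without KO replicate 2 and 662 without Il4null_KO replicate 1, which is below the 724 that would by chance. edgeR called 0 and DESeq2 called 386, of which 281 were higher. The genes with the smallest p were Arhgap5 (log2 fold change 3.95 ± 0.41, adjusted p = 0.203), Slc4a7 and Top2b among the higher and Csrnp1, Pik3ip1 and Ecm1 among the lower, the last 5 with adjusted p = 0.321. Arhgap5, Slc4a7 and Top2b have long transcripts, of 9323, 8132 and 10335 nucleotides, and the difference followed transcript length across genes in this comparison, as in the others. Within the deeper library set, with the repeat KO libraries alone, all 7 list calls held. The medians were then -1.03 for hypoxia, -1.33 for tissue repair, -0.44 for IL-4 and STAT6, 1.42 for adhesion, -1.46 for stress, -2.16 for neutrophil and -1.54 for epithelium genes. With the epithelium mean as a covariate, the adhesion and epithelium calls were lost (adjusted p = 0.368 and 0.629), with medians of 0.28 and -0.10. The stress call was lost with the first KO libraries only (0.0655), without the repeat library of KO replicate 2 (0.064) and with quantile normalization (0.183).

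Without KO replicate 1 the IL-4 and neutrophil calls were lost (adjusted p = 0.0696 and 0.251), and without KO replicate 2 the stress and epithelium calls (0.0618 and 0.0631). Without Il4null_KO replicate 1 the adhesion and epithelium calls were lost (0.139 and 0.279), and without Il4null_KO replicate 2 the IL-4, tissue repair and stress calls (0.0744, 0.0744 and 0.119). In 4 of these 9 lost calls the median shrank by more than 1.5 times: adhesion (0.21), neutrophil (-1.68) and epithelium in both fits (-0.86 and -0.41).

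The comparison of Il4null with WT asked what loss of Il4 does where Tgfbr2 is intact. At the preset correlation 5 T cell state lists passed, none of which did with an estimated correlation (each adjusted p = 0.721) or with a term for the library set. The exhaustion and checkpoint list was higher in Il4null in 10 of 12 members, with a median of 0.87 (camera adjusted p = 0.000858). Tox, a transcription factor gene of exhausted T cells, had 935 and 1748 normalized counts in WT and 4804 and 2678 in Il4null. The naive and central memory list was higher in 13 of 14 members, with a median of 0.48, and the type 17 helper list in 10 of 13, with a median of 0.81 (camera adjusted p = 0.0134 and 0.0278). The cell cycle list was lower in 18 of 22 members, with a median of -0.41, and the interferon-stimulated list in 16 of 18, with a median of -0.42 (camera adjusted p = 0.00143 and 0.00579). Ccnb1, a mitotic cyclin gene (log2 fold change -1.17 ± 0.42), and Usp18, an interferon-induced protease gene (-1.04 ± 0.46), led them. In these lists 0 members passed over the list alone.

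With these lists, the macrophage and dendritic cell lists were higher, with medians of 1.79 and 1.60 (camera adjusted p = 0.000225 and 0.0255), and the dissociation stress list was lower, with a median of -0.78 (0.0255). They had adjusted p = 0.721, 0.751 and 0.721 with an estimated correlation. No gene passed limma, and 591 had an unadjusted p under 0.05 (388 to 1303 in the fits that left out 1 replicate). The main count of 591 was below the 724 that would by chance. edgeR called 0 and DESeq2 called 29. Lower genes called by DESeq2 included Cd8a, a CD8 T cell gene (log2 fold change -8.23, adjusted p = 6.92e-08), Ski (-2.48) and Tada2b (-2.56). By limma the smallest p belonged to Srcap, encoding a chromatin remodeller, with 689 and 676 normalized counts in WT and 3451 and 3610 in Il4null (adjusted p = 0.358). With a term for the library set, its log2 fold change went from 2.37 ± 0.30 to 0.69. In KO, Srcap had 690 and 671 in the first libraries and 2821 and 1694 in the repeats, so within one RNA it differed between library sets. Eif4ebp2, a translation repressor gene, had 316 and 323 in the first KO libraries and 1654 and 2623 in the repeats, and 266 and 120 in WT against 1991 and 1903 in Il4null.

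No library set held both genotypes. List calls with a term for the set came from cameraPR, so they mix a change of test with the set term. In a fit with a term for the set, which the KO libraries bridge, the macrophage call (median 1.49) and the stress call (-1.24) held, while the type 17, naive, exhaustion, cell cycle, interferon and dendritic calls were lost (adjusted p = 0.137, 0.37, 0.143, 0.0663, 0.226 and 0.0928). Their medians were then 0.92, 0.45, 0.65, -0.20, -0.17 and 1.90, so the cell cycle and interferon differences shrank, while the loss of the other 4 calls does not show that the library set explains them. The stress call was lost with quantile normalization (0.338) and with the length trend removed (0.0521), and the type 17 call with the repeat KO libraries only (0.0595) and with all 10 libraries (0.0528). Without WT replicate 1 the naive, exhaustion, stress, macrophage and dendritic calls were lost (0.0932, 0.236, 0.45, 0.183 and 0.874), and without WT replicate 2 the type 17, naive, cell cycle and interferon calls (0.162, 0.0723, 0.777 and 0.289). Without Il4null replicate 1 the naive and stress calls were lost (0.465 and 0.713), and without Il4null replicate 2 the type 17, cell cycle, interferon, macrophage and dendritic calls (0.346, 0.346, 0.0578, 0.8 and 0.713). In 10 of these 16 lost calls the median shrank by more than 1.5 times or turned.

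The interaction asked whether Tgfbr2 deletion had another effect on the Il4-deficient background. No gene passed limma (510 had an unadjusted p under 0.05, and 294 to 1593 in the fits that left out 1 replicate), edgeR called 0 and DESeq2 called 35. The main count of 510 was below the 724 that would by chance. Tgfb1, which encodes the TGF-beta ligand, was among the 3 genes with the smallest p. It was higher in KO than in WT and lower in Il4null_KO, with 2650 and 2813 normalized counts, than in Il4null, with 3413 and 3881 (interaction -2.06 ± 0.40, adjusted p = 0.988). Hoxb2 and Pgr, the progesterone receptor gene, were the other 2, with at most 198 normalized counts in any replicate. At the preset correlation 9 lists passed, and none did with an estimated correlation (smallest adjusted p = 0.681). The IL-4 and STAT6 response (median -0.85), exhaustion (-0.92), hypoxia (-0.78) and tissue repair (-0.95) lists were among the 7 with a lower effect in the Il4-deficient cells, and the cell cycle list (0.65) was 1 of 2 with a higher effect. The IL-4 call was lost without WT replicate 1 (adjusted p = 0.36), and the hypoxia call without WT replicate 2 (0.551) or Il4null replicate 2 (0.111). The tissue repair call was lost without Il4null replicate 2 (0.221) or Il4null_KO replicate 2 (0.107), and the cell cycle call without WT replicate 2 (0.439), KO replicate 2 (0.241) or Il4null replicate 2 (0.356). The hypoxia call was also lost with the epithelium covariate (0.121), as was the cell cycle call (0.171), which was lost with the repeat KO libraries only too (0.0729). The exhaustion call was lost without WT replicate 1 (0.429), KO replicate 1 (0.591, with the median turned to 0.21), Il4null replicate 1 (0.0545) or Il4null_KO replicate 2 (0.209). Over all 9 lists, the median shrank by more than 1.5 times or turned in 19 of the 27 calls lost by leaving out 1 replicate. In the IL-4 list, Cish had the smallest p (-1.85 ± 0.52), with 4355 and 4789 normalized counts in WT, 7192 and 10779 in KO, 9847 and 6269 in Il4null, and 5173 and 3407 in Il4null_KO.

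The TGF-beta response list did not pass in the interaction (median 0.34, mean -0.05, camera adjusted p = 0.386), nor did the type 2 helper list (median -1.33, adjusted p = 0.104). Pparg, a nuclear receptor gene used by type 2 cells, had the smallest p of that list, with 113 and 407 normalized counts in KO and 35 to 169 in the Il4-deficient replicates.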

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

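The tests on neutrophil RNA, NK cell RNA, the library set for transcript length and the integrity of the KO RNA were chosen only after the result was seen, as were the covariate for epithelial RNA and the removal of the length trend. For 9 gene lists, the effect of Tgfbr2 deletion differed between the Il4 backgrounds by the interaction test of limma and camera at the preset correlation. None passed with an estimated correlation, where each had adjusted p = 0.681. The IL-4 and STAT6 response (median -0.85), hypoxia and glycolysis (-0.78), and tissue repair and growth factor (-0.95) lists had a lower effect on the Il4-deficient background, and the cell cycle list (0.65) a higher one, each with adjusted p = 0.00622. The exhaustion and checkpoint (-0.92), macrophage and monocyte (-1.56), and neutrophil (-2.31) lists had adjusted p = 0.00983. The interferon-stimulated list (0.56) had adjusted p = 0.0321, and the mammary and tumour epithelium list (-0.89) had adjusted p = 0.0481.

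Each of the 9 calls was lost in at least 1 fit that left out a replicate. The macrophage call was lost without WT replicate 1 (adjusted p = 0.429), Il4null replicate 2 (0.919) or Il4null_KO replicate 2 (0.311). The neutrophil call was lost without WT replicate 1 (0.0937), KO replicate 1 (0.312), Il4null replicate 2 (0.28) or Il4null_KO replicate 1 (0.0743), and with the repeat KO libraries only (0.0969). The interferon call was lost without WT replicate 2 (0.219), KO replicate 2 (0.898), Il4null replicate 2 (0.173) or Il4null_KO replicate 1 (0.0925), and the epithelium call without WT replicate 2 (0.869), KO replicate 2 (0.233), Il4null replicate 2 (0.465) or Il4null_KO replicate 1 (0.504). The interferon call was also lost with the repeat KO libraries only (0.102), all 10 libraries (0.056), the library set term (0.0616) and the epithelium covariate (0.254). The epithelium call was also lost with the filter at 50 (0.0548), quantile normalization (0.0655), the length trend removed (0.0842) and the epithelium covariate (0.63). The epithelium covariate ended the hypoxia (0.121) and cell cycle (0.171) calls too, and the repeat KO libraries only the cell cycle call (0.0729). Without Il4null replicate 2, 3 lists passed in place of 9.

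Mmp9 and Klrg1 were higher, and Ahr lower, in the Tgfbr2-deleted replicates on both Il4 backgrounds. Against neutrophil RNA as the source of Mmp9 on the Il4-deficient background, the other 7 neutrophil members had a median of 0.57 (median absolute deviation 0.66) against 3.99 for Mmp9, and S100a8 had 19 and 70 normalized counts in Il4null and 13 and 121 in Il4null_KO. Against NK cell RNA as the source of Klrg1 on the other background, the 6 NK members had a median of -0.55 against 3.86 for Klrg1. Their median absolute deviation was 1.63, and they went both ways, with 2 higher, 4 lower and a mean of 0.06. Their member Tyrobp had 266 and 445 in WT and 222 to 385 in KO. Neutrophil RNA may still add to Mmp9 in KO against WT, where the other 7 members had a median of 3.05 (median absolute deviation 1.90) against 5.70. The neutrophil list mean, Mmp9 included, was 9.99 and 10.1 in the libraries of KO replicate 1 but 7.23 and 5.25 in those of replicate 2. WT had 5.29 and 5.62. Without KO replicate 1 the Mmp9 log2 fold change was 6.35, and without replicate 2 it was 5.05. This argues against neutrophil RNA as the main source of Mmp9 in KO replicate 2. NK cell RNA cannot be told apart from T cell RNA as the source of Klrg1 in Il4null_KO against Il4null. The 6 NK members there had a median of 0.85 but went both ways (median absolute deviation 2.32). CD8 T cell RNA was not tested as a source of Klrg1 and stays open. By DESeq2, the CD8 T cell gene Cd8a had an interaction of 7.53 (adjusted p = 0.0037), while limma called no gene there. The sort for CD4 selects against these cell types, but its purity was not measured and RNA of other cell types was present. A fit of 2 groups that ignored Il4 gave 5 genes where the fit of all 4 genotypes gave 3. Of the 35 splits of the 8 replicates into 4 and 4, 2 gave as many, the real one included. By this count chance could not be excluded. The highest other split, with 58 genes, was tied to a structure of the samples only after it was seen, which does not change the count. Every remaining split gave 0. An effect of Tgfbr2 deletion is thus a hypothesis.

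Long transcripts were lower in KO than in Il4null_KO, with a median log2 difference of -0.40 in the shortest of 5 bins of genes and 0.57 in the longest. Against the library set as the whole cause, the Spearman correlation of the difference with length across genes was 0.325 with the repeat KO libraries alone and 0.408 with all. The integrity or amount of the KO RNA and the genotype cannot be told apart, since 4 of 4 KO libraries had a lower correlation with length than every Il4null_KO library and the design holds no KO RNA of another quality. These correlations, of each library's deviation from the gene means, were -0.41 and -0.39 in the first KO libraries, -0.20 and -0.21 in the repeats, and 0.32 and 0.21 in Il4null_KO. The WT replicates, of one genotype and depth set, had -0.21 and 0.29, so a difference in this trend did not need a difference in genotype. An effect of Il4 on long transcripts stays open and untested, and the other comparisons also followed length, with correlations of -0.309 in KO against WT and 0.379 in Il4null against WT.

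The hypoxia and glycolysis list was lower in Il4null_KO than in KO by a median of -1.02. With the epithelium mean as a covariate it stayed at -0.65 (camera adjusted p = 0.00145), with the trend on transcript length removed at -0.78 (0.000128), and with the repeat KO libraries alone at -1.03 (4.92e-05). These values argue against epithelial RNA, transcript length or the library set as the whole cause. The list mean on the log2 scale was 11.25 to 11.97 in the KO libraries and 10.48 and 10.66 in Il4null_KO. The WT replicates, of one genotype and depth set, had 11.98 and 10.48, so a difference of this size did not need a difference in genotype. Across the alternatives at the preset correlation, the median ran from -1.18 to -0.65 with adjusted p up to 0.00475, but with an estimated correlation adjusted p was 0.697. The neutrophil (-2.61) and dissociation stress (-1.39) lists were lower in the same comparison, so handling or tumour oxygen that differed between replicates stays open beside an effect of Il4, and neither was tested.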

How the results depend on the processing

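The library set term, the epithelium covariate, the removal of the length trend, KO replicate 2 without its repeat library, and all values of the mean effect over both backgrounds were chosen only after the result was seen. Of 4605 values of named genes under alternatives, 4485 kept their direction and side of the threshold, 66 newly passed, 36 no longer passed and 18 reversed. Most of these genes had not passed in the main fit, so staying on their side was largely fixed in advance. Only Mmp9 in KO against WT, which passed in 12 of 25 alternatives, and the 3 genes over both backgrounds could stop passing. Of 946 list values, 795 kept both, 145 no longer passed and 6 reversed. Where a cause is not named below, the cause was not tested. For KO against WT, which had 1 gene, the count was 2 with quantile normalization, 2 without a variance trend (Tmem132e and Efcc1, not Mmp9), 2 with all 10 libraries, 2 with the library set term, 6 with the epithelium covariate and 527 by DESeq2. It was 0 with only the genotypes compared, the repeat KO libraries only, the replicate block or edgeR. For Il4null_KO against Il4null the count went from 0 to 1 with quantile normalization, all 10 libraries or the epithelium covariate (Klrg1 in each) and with KO replicate 2 without its repeat library (Mmp9), and to 51 by DESeq2. DESeq2 also gave 386 genes for Il4null_KO against KO, 29 for Il4null against WT, 35 for the interaction and 18 for the overlap of both deletion effects. For these limma gave 0, which for the overlap was fixed by the 0 genes of Il4null_KO against Il4null. Over both backgrounds, the count of 3 became 8 with quantile normalization, 0 without a variance trend, 7 with all 10 libraries, 19 with the epithelium covariate and 331 by DESeq2, 4 with the library set term or the length trend removed, and 2 without a filter, with the repeat KO libraries only or by edgeR, which ended the Ahr call. Of 24 alternatives Ahr passed in 11, and Mmp9 and Klrg1 in 19. With an estimated correlation the number of lists was 0 in each of the 5 comparisons. For KO against WT it went from 9 to 15 without a filter and to 14 with the library set term, for Il4null_KO against Il4null from 10 to 5 with the epithelium covariate, and for Il4null against WT from 8 to 2 with the library set term. The list counts with the library set term came from cameraPR, so the change of test may add to these shifts. Leaving out 1 replicate gave 0 to 0 genes in each of the 5 comparisons and in the overlap, and 0 to 4 over both backgrounds. A genotype left with 1 replicate was assumed to vary like the others. It gave 5 to 11 lists for KO against WT, 6 to 13 for Il4null_KO against Il4null, 4 to 9 for Il4null_KO against KO, 4 to 10 for Il4null against WT and 3 to 12 for the interaction. The log2 fold change of Tgfbr2 reversed in KO against WT with the repeat KO libraries only (0.11) or the length trend removed (0.24), and in Il4null_KO against KO with the repeat KO libraries only (-0.089), the library set term (-0.089) or the length trend removed (-0.47). In Il4null_KO against Il4null, Il13 reversed with quantile normalization (0.88), edgeR (0.12) or DESeq2 (0.13), and without Il4null_KO replicate 2 (-1.46 to 0.85 over the fits that left out 1 replicate). Over the same fits, Il4 ran from -1.09 to 0.20, reversed without Il4null_KO replicate 2, and Pdcd1 from -0.78 to 0.052, reversed without Il4null replicate 1. In Il4null against WT, Tada2b (0.0053) and Nr4a3 (-0.31) reversed with the library set term. There, Ccl5 ran from -0.082 to 1.94, reversed without Il4null replicate 1, and Vegfa from -2.74 to 0.054, reversed without WT replicate 1. The Il5 interaction ran from -3.59 to 1.81 and reversed without KO replicate 2 (0.51), Il4null replicate 1 (0.80) or Il4null_KO replicate 2 (1.81). Of the lists in Il4null_KO against Il4null, the cytotoxic median ran from -0.36 to 1.74 and the macrophage median from -2.83 to 0.032, both reversed without Il4null replicate 2. The epithelium median reversed with the epithelium covariate (0.028), which removes that list's own mean, and also turned without Il4null replicate 2 (0.025) or Il4null_KO replicate 1 (0.13). Other medians that turned while their test kept its direction were exhaustion in KO against WT without KO replicate 1 (-0.0016), core T cell in Il4null_KO against Il4null without Il4null replicate 2 (-0.0041), type 17 in Il4null against WT without WT replicate 2 (-0.077) and exhaustion in the interaction without KO replicate 1 (0.21). In the interaction, the interferon median ran from -0.040 to 1.19, reversed without KO replicate 2. The epithelium median there ran from -2.28 to 0.18 and was 0.63 with the epithelium covariate, and the direction of its test also reversed without WT replicate 2 (median -0.11). Quantile normalization moved the median of all genes in KO against WT from -0.07 to 0.03, and the Mmp9 value there from 5.70 to 5.66.

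The replicate numbers did not pair the samples of all 4 genotypes. Correlations across genes of the difference between replicates 1 and 2 were 0.192 to 0.236 among KO, Il4null and Il4null_KO, and -0.202, -0.335 and -0.358 for WT with these. The WT replicates thus lay the other way round on an axis that the other genotypes shared. The block by number sets WT against that axis, and no block with the WT numbers exchanged was fitted. With the replicate number as a block, Mmp9 in KO against WT had adjusted p = 0.175, against a range of 8.89e-27 to 0.752 over its alternatives. With this block the epithelium call of the interaction was also lost (adjusted p = 0.0526). Over both backgrounds it left 2 genes in place of 3, Mmp9 and Klrg1 (both 0.049), and ended the Ahr call (0.216).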

Other observations

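The sample split below and its genes were chosen only after the result was seen. Among the lists that did not pass at the preset correlation, adjusted p ran from 0.0635 to 0.955 for 18 lists in KO against WT, from 0.068 to 0.985 for 17 in Il4null_KO against Il4null, from 0.104 to 0.994 for 20 in Il4null_KO against KO, from 0.052 to 0.979 for 19 in Il4null against WT, and from 0.0902 to 0.923 for 18 in the interaction.

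The split with 58 genes set WT replicate 1 and replicate 2 of KO, Il4null and Il4null_KO against the others, 1 replicate of each genotype on each side, which points to a structure of the samples. Col4a1, a basement membrane collagen gene, had 3384 and 168 normalized counts in WT, 1 and 3997 in KO, 23 and 2867 in Il4null, and 0 and 682 in Il4null_KO. Eln, the elastin gene, had 217 and 16 in WT, 1 and 548 in KO, 0 and 874 in Il4null, and 0 and 820 in Il4null_KO. Mfge8, a secreted glycoprotein gene of mammary epithelium, had 27940 and 1572, 4798 and 16684, 1476 and 9718, and 1075 and 9291 in the same order.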
